A study of Homo sapiens with 10 samples.

How the data were processed

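A549 cells, a human lung epithelial line, were cultured in 6-well plates and given 0 or 200 µg/ml crystalline silica for 24 hours in medium without serum, per the labels' protocols. RNA was purified on columns with DNA digestion, and biotin-labelled cRNA was hybridised to Illumina bead arrays. Of the 10 samples, 5 were controls and 5 received silica, and each group was taken from the sample titles.

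The deposited table of signals holds, per the file headers, a mean bead intensity, a detection p-value, a bead standard error and a bead number for each array and gene name, with 37846 rows. The intensity was not normalized by the authors, as its medians differ between arrays, and shows no sign of background subtraction, as they lie far above 0. Bead numbers that are not whole show that 6975 rows are means over several probes of a gene, and the other 30871 rows stand for 1 probe. The submitters' processing notes name BeadStudio, lumi and limma, without versions or roles. The authors' processed values are a second deposited table of 13527 rows on a log2-like scale, used here only as an alternative. Set against log2 of the same array's intensity, its columns correlated at 0.992 to 0.997. Their medians were 7.41 to 7.42, so the values were not centred, and the transform at low intensity is not given in the sources used here. Chip positions and scan dates were not given either.

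Rows with a symbol numbered 25200. The other 12646 carry only a transcript cluster name. Symbols were updated through the Entrez gene IDs of the file, of which 20467 matched the RefSeq gene table of GRCh38.p14, used for names and gene lengths only. This also restored 24 symbols that a spreadsheet had turned into dates. The files name no genome build, so chromosomes are those of the file and no coordinates are given.

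Background was estimated on each array by the normexp model of limma from the detection p-values, an offset of 16 was added, and the arrays were quantile normalized and taken to log2. The model was fitted on rows of 1 probe and applied to all rows, since the detection p-value of an averaged row is on another scale. This was not the plan. The planned fit on all rows was run first and its result seen (896 genes past 5% FDR, 293 of them past 1.5-fold, against 998 and 722), and the fit was then changed because its background levels lay above 80.9% to 82.9% of the rows of 1 probe. Background levels were 62.2 to 75.1 on 8 arrays, and 196 and 203 on the 2 bright arrays, replicate 2 of each group. The offset shrinks the fold changes of genes near background. Their size also depends on the background fitted, and the other treatments of the background gave smaller fold changes. The reported fold changes are thus not lower limits. Rows were kept with a detection p-value under 0.05 on at least 5 of the 10 arrays. A gene is called above background on an array where its detection p-value is under 0.05. A row of several probes can fail this at an intensity above the level of detection. Its count of arrays then does not show low expression. The row with the highest mean was kept where a symbol had several, which left 10137 genes. This filter also removed 691 rows of several probes whose intensity lay above the level of detection on at least 5 arrays, CDKN1A among them, so a filter on signal was added as an alternative after seeing the data.

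Silica and control arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by the method of Benjamini and Hochberg. All p-values are two-sided. Tested on simulated data with the real means and spreads of 10137 genes, of which 200 were changed, the comparison of silica with control recovered 36% of the 100 genes changed 1.5-fold and 84% of the 100 changed 2-fold, and 6.25% of its calls were false. The simulated noise was independent between genes and drawn once, so these rates need not hold on the real arrays. A gene not above background on any array of a group has a bound in place of a fold change. The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own value and the lowest value of a detected row of 1 probe.

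Before the data were examined, 33 gene lists were fixed for an epithelial cell meeting particles. They cover NRF2 targets, metallothioneins, NF-kB targets, immediate early genes, EGF receptor ligands, the ATF4 response, chaperones, heat shock, p53 targets, apoptosis, DNA replication, mitosis, histones, cholesterol and fatty acid synthesis, hypoxia, lysosome, autophagy, TGF-beta targets, proteases, interferon response, junctions, mesenchymal markers, actin, distal lung markers, acute phase, oxidative phosphorylation, ribosomal proteins, ribosome assembly, xenobiotic metabolism, inflammasome, leukocytes, and fibroblasts and endothelium. Lists with at least 5 measured members were tested with camera at a correlation of 0.01, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. The genes named were fixed by rule as the 10 largest increases and decreases past 5% FDR with an approved symbol and groups that did not overlap, up to 4 members per list with the largest change (or, in a list with none past the threshold, the 2 with the smallest p), and HMOX1, CXCL8, IL6, CDKN1A, MKI67 and GAPDH. A few genes outside the rule were named after their values were seen, and are marked. Some genes are not reported here, for reasons unrelated to their values, and still count in the totals and lists.

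The alternatives tried were other background corrections, normalizations, detection filters and ways to join rows, the authors' values, blocks by the numbers in titles and descriptions, array weights, a moderated trend and leaving out each array. The background fitted on all rows, planned as the main setting, became an alternative after its result was seen. Those added after seeing the data were signal level as a block, leaving out the 2 bright arrays, and the filter on signal.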

Results

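The series holds gene expression profiles of 10 cultures of A549, a human lung epithelial line derived from an adenocarcinoma. The cells were kept for 24 hours in serum-free medium with no crystalline silica (control, n = 5) or with crystalline silica at 200 µg/ml (silica, n = 5). The series title gives the mechanisms by which silica particles injure the lung as the subject. Each RNA was read on 1 Illumina bead array. The labels do not say whether replicates came from separate experiments, so the p-values measure only the spread between these samples, part of which may be technical.

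Between 29.2% and 33.5% of the 37846 rows per array were above background, at a mean of 17.3 to 20.9 beads per probe. The median raw intensity was 66.6 to 80.3 on 8 arrays, and 212 and 219 on replicate 2 of the control and silica groups. The first principal component held 34% of the variance after normalization and parted the silica arrays (scores of 16.7 to 21.7) from the controls (-38.6 to -13). Control replicate 1 stood apart from the other controls. Its second component score was 34.8, against -16.8 to -11.2 for the other 4, and its mean correlation with its own group was 0.956, against 0.975 to 0.981 for the other 9 arrays. No pair of arrays correlated above 0.988, so none was counted as a duplicate.

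**Figure D1:**
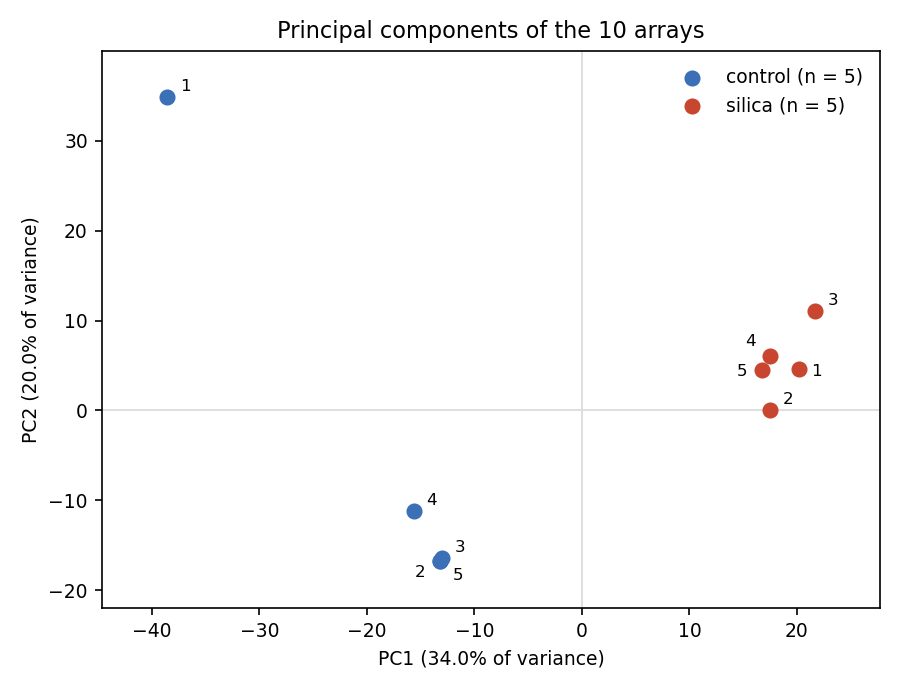
Principal components of the normalized log2 intensities of 10137 genes on the 10 arrays, 1 point per array with its replicate number, PC1 on the horizontal and PC2 on the vertical axis (scores, with the percent of variance). The silica arrays lie at PC1 scores from 16.7 to 21.7, and control replicate 1 lies at -38.6 on PC1 and 34.8 on PC2.

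Silica was compared with no silica after 24 hours to find which transcripts the particles changed. Genes of inflammation led the increases. The transcript of IL6 (chromosome 7), a cytokine of inflammation, was not above background on any control array and was at least 31.5-fold higher in silica on the background-corrected scale used here (log2 intensity 4.76 ± 0.10 to 9.98 ± 0.24, mean ± SD, n = 5 per group, adjusted p = 3.69e-11). CXCL8 (chromosome 4), the neutrophil chemokine interleukin 8, rose 21-fold, from 9.35 ± 0.21 to 13.75 ± 0.14 (adjusted p = 1.61e-10). CXCL2 (chromosome 4) and CCL20 (chromosome 2), chemokines for neutrophils and for lymphocytes and dendritic cells, rose 17.7-fold and 10.2-fold, and each was above background on 2 of the 5 control arrays. CSF2 (chromosome 5), the granulocyte and macrophage growth factor, was not above background on any control array and was at least 6.59-fold higher on the same scale (adjusted p = 1.74e-09). These bounds depend on the background. The fitted log2 fold changes of IL6 and CSF2 were 3.22 and 1.55 without background correction and 2.72 and 0.46 with the planned background on all rows, against 5.22 and 3.28 here. The mitochondrial superoxide dismutase SOD2 (chromosome 6) rose 8.91-fold, and TNFAIP3 (chromosome 6), an inhibitor of NF-kB signalling, rose 7.36-fold and was above background on 4 of the 5 control arrays. The transcription factors FOSB (chromosome 19) and EGR1 (chromosome 5) rose 10.5-fold and 7.04-fold, and the secreted glycoprotein STC2 (chromosome 5) rose 8.86-fold. For CXCL2, CCL20, SOD2, TNFAIP3, FOSB, EGR1 and STC2, the standard errors of the log2 fold changes lay between 0.13 and 0.23, and the largest adjusted p was 4.13e-07.

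The largest decreases were smaller than the largest increases. CIDEC (chromosome 3), a lipid droplet protein, fell by 2.04 on the log2 scale, from 7.59 ± 0.35 to 5.55 ± 0.23 (n = 5 per group, adjusted p = 6.07e-06). Next came TM4SF4 (chromosome 3), a tetraspanin-like membrane protein, with a log2 fold change of -1.87 ± 0.16 (± SE), and AXIN2 (chromosome 17), a target and inhibitor of Wnt signalling, with -1.79 ± 0.14. The cell adhesion proteins CDH1 (E-cadherin, chromosome 16) and CDH17 (chromosome 8) had log2 fold changes of -1.64 ± 0.17 and -1.64 ± 0.17. For the bile acid conjugating enzyme BAAT (chromosome 9) the log2 fold change was -1.63 ± 0.18, for the type I collagen chain COL1A1 (chromosome 17) -1.61 ± 0.18, and for RAP1GAP (chromosome 1), which switches off the GTPase RAP1, -1.59 ± 0.15. The lysophosphatidic acid receptor LPAR5 (chromosome 12) and the zinc finger protein ZNF467 (chromosome 7) completed the 10 with -1.70 ± 0.27 and -1.65 ± 0.20. The largest adjusted p of these 10 was 0.00114, that of LPAR5. In silica, CDH17 was above background on 3 arrays and CIDEC, LPAR5 and COL1A1 on 4. CIDEC was above background on 4 control arrays.

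**Figure D2:**
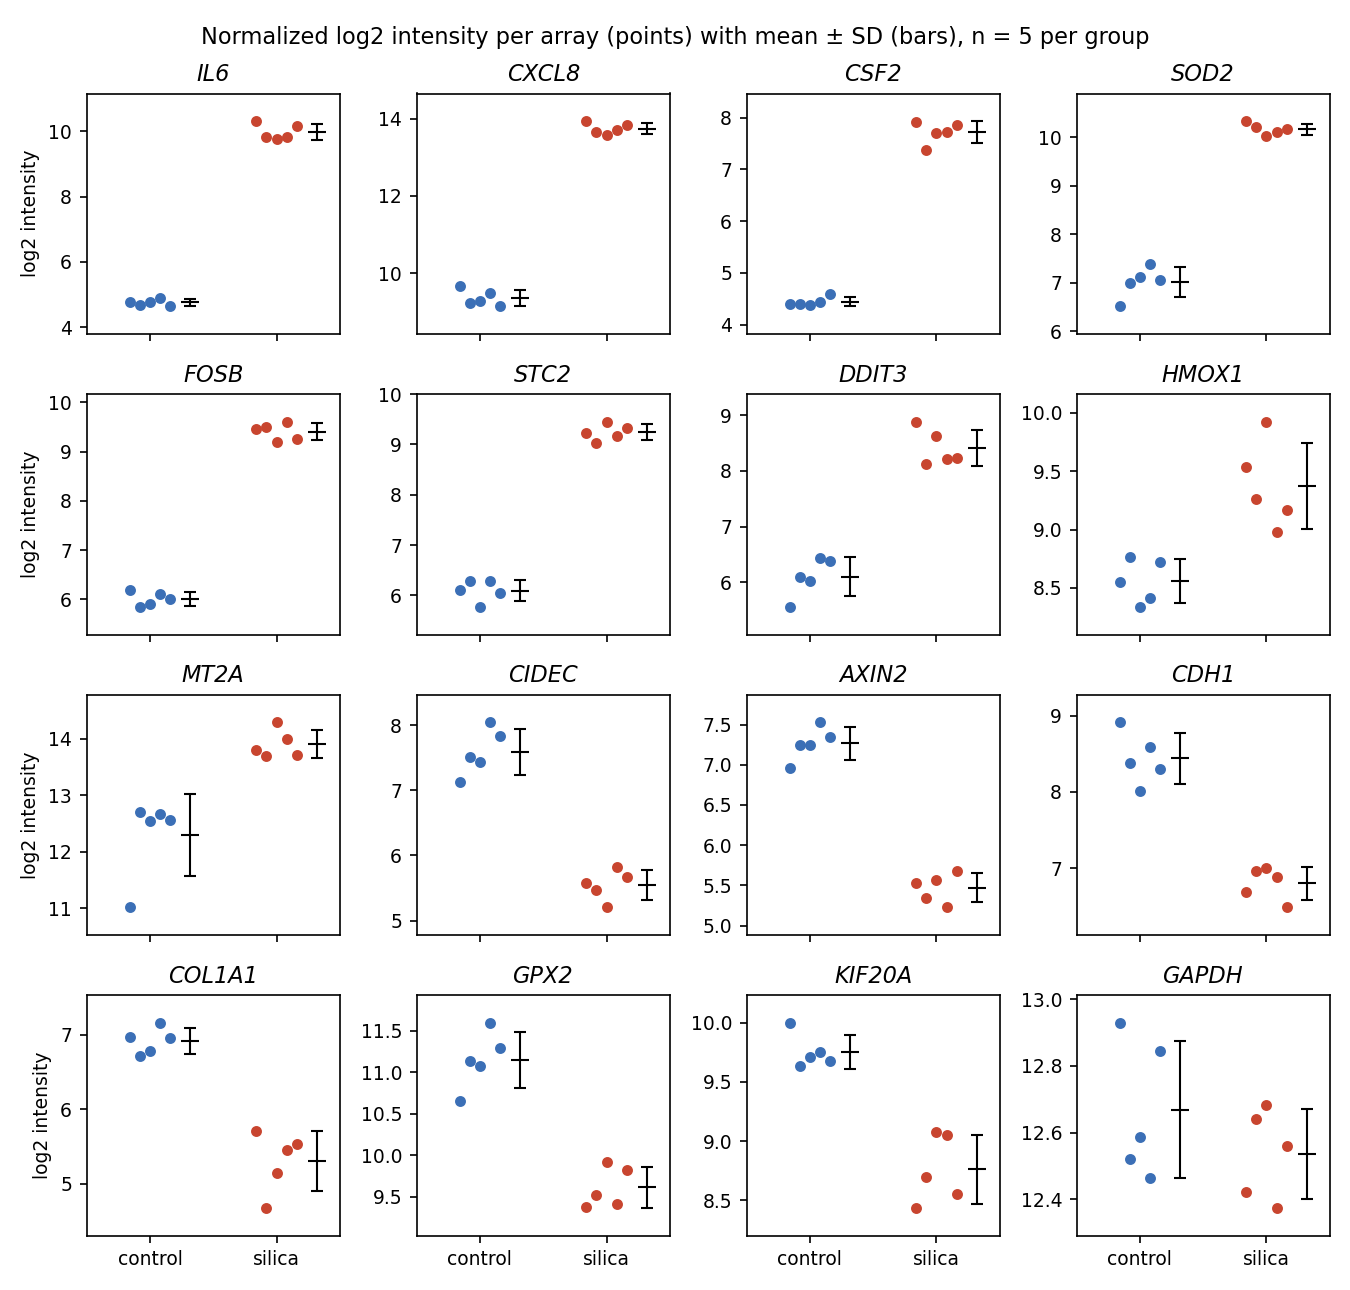
Normalized log2 intensity of 16 named genes, 1 panel per gene with its own vertical axis, which does not start at 0, showing 1 point per array and the mean ± SD of 5 arrays per group. The IL6 values rise from a mean of 4.76 in control to 9.98 in silica, those of CDH1 fall from 8.44 to 6.80, and those of GAPDH overlap.

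Over all 10137 genes tested with limma, 998 passed a 5% false discovery rate (FDR), of which 480 were higher and 518 lower in silica. Of these, 722 changed at least 1.5-fold (355 higher, 367 lower), and 124 higher and 69 lower genes changed at least 2-fold. Of the 722, 25 were not above background on any array of a group, and for 12 of these the bound lay under 1.5-fold or none could be given. Of the genes past 2-fold, 11 were not above background on any array of a group. For 4 of these the bound lay under 2-fold or none could be given. The values of the 5 silica arrays did not overlap those of the 5 controls for 494 higher and 581 lower genes, together 10.6% of all genes, where chance gives 0.794%. With median scaling in place of quantile normalization, 705 genes passed and the share of higher genes was 31.9%, against 48.1% with quantile normalization, and the median log2 fold change of all genes was -0.09. Of the genes named in the text, the calls of FTH1, HERPUD1, TNFRSF10B, MCL1, APAF1, EBP, ELOVL6, SCD5, SQSTM1, OPTN, RRP12, RRS1, TIPARP, TICAM1, ADAM10, CDC25B, XBP1, CD59 and ADM ended with median scaling (adjusted p from 0.0509 to 0.242). Without control replicate 1, 1136 genes passed 5% FDR. With signal level as a block 915 passed, and within the 8 other arrays 281 higher and 268 lower genes did. In the bright pair, 1 array per group and so without a test, 96.4% of the genes called on those 8 arrays differed in the same direction, against 64.1% of the genes not called on them. The count past 1.5-fold depended on the processing, and differed between treatments of the background. Its 722 genes come from a background fitted on rows of 1 probe, a choice made after the planned fit on all rows had given 293. It was 293 without background correction. In the authors' processed values, which also differ in their rows and in a transform that is not given, it was 211. Every fold change printed shares this dependence. Over the genes called, the median ratio of the log2 fold change to the one reported was 0.328 with the background on all rows, 0.656 without background correction, 0.77 with an offset of 50 and 0.525 in the authors' values.

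Of the 26 measured NF-kB targets, the cytokines, chemokines and feedback inhibitors fixed as a list before the data were examined, 25 rose and none fell (26 rose when adjusted over the list alone, median log2 fold change 2.17, adjusted p = 2.82e-49). The median was 2.06 with the 5 members not above background on any control array set at their bounds. IL1B, an inflammatory cytokine among them, was at least 4.17-fold higher on the background-corrected scale (adjusted p = 7.79e-09). With the planned background on all rows the median of the list was 0.63, and without background correction it was 1.33. Immediate early and AP-1 genes, which MAP kinase signalling induces, followed with 12 of 24 higher and none lower (16 higher when adjusted over the list alone, median log2 fold change 0.57, adjusted p = 5.53e-16). Beside FOSB and EGR1, the AP-1 subunit FOSL1 had a log2 fold change of 1.89 ± 0.17 and the ERK phosphatase DUSP5 one of 1.68 ± 0.15. Among proteases and their inhibitors 6 of 11 rose and none fell (7 higher when adjusted over the list alone, median log2 fold change 0.77, adjusted p = 2.4e-06). The stromelysin MMP10 was not above background on any control array and was at least 4.99-fold higher on the background-corrected scale. The fitted log2 fold changes of IL1B and MMP10 were 1.09 and 1.19 without background correction and 0.26 and 0.32 with the background on all rows, against 2.58 and 2.70 here. The urokinase receptor PLAUR rose by 1.12 ± 0.14 on the log2 scale. EGF receptor ligands and their machinery moved both ways, with 4 of 9 higher and 2 lower, the same counts as when adjusted over the list alone (median log2 fold change 0.52, adjusted p = 0.00612, adjusted p = 0.0959 with an estimated correlation). Without silica replicate 1 the median was 0.34. The ligands HBEGF (1.50 ± 0.14), EREG (1.21 ± 0.20) and TGFA (0.74 ± 0.14) and the receptor EGFR (0.74 ± 0.13) rose. The receptor ERBB3, not above background on any silica array and at least 1.14-fold lower on the background-corrected scale, and the sheddase ADAM10 (-0.49 ± 0.14, above background on 3 control and 2 silica arrays), both named after their values were seen, fell. The call of ERBB3 ended with the background on all rows (adjusted p = 0.0612) and in the authors' values (adjusted p = 0.0785), in a range over all alternatives from 0.0029 to 0.0785. The mean log2 intensities of ADAM10 were 6.86 in control and 6.37 in silica. The call of ADAM10 ended without control replicates 2 or 4 or silica replicates 1, 2 or 3 (adjusted p from 0.0549 to 0.1). Above background on the controls were FOSL1 on 3, HBEGF and EGFR on 4 and TGFA on 2 arrays. The mean log2 intensity of EGFR in control was 6.62.

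The integrated stress response was tested next. In the ATF4 and amino acid list 15 of 22 were higher and none lower (17 higher and 1 lower when adjusted over the list alone, median log2 fold change 0.82, adjusted p = 5.86e-16). Apart from STC2, the log2 fold change was 2.32 ± 0.19 for the transcription factor DDIT3 (CHOP), 1.99 ± 0.15 for PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2 alpha, and 1.67 ± 0.14 for asparagine synthetase, ASNS. Chaperones of the endoplasmic reticulum were not called as a list (median log2 fold change -0.09, adjusted p = 0.596), with 3 of 19 higher, DNAJB9 (95% interval of the log2 fold change 0.61 to 1.39), HERPUD1 (0.55 ± 0.12) and the transcription factor XBP1 (0.49 ± 0.13, named after its value was seen), and 2 lower, CRELD2 (-0.67 ± 0.15) and PDIA4 (-0.73 ± 0.18). The call of XBP1 ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 3 or 4 (adjusted p from 0.0531 to 0.0839). The call of PDIA4 ended without control replicates 4 or 5 or silica replicates 1, 3 or 5 (adjusted p from 0.0501 to 0.0609). Adjusted over the list alone, 3 were higher and 5 lower. The list's median was -0.19 without control replicate 1, and -0.16 to -0.14 without control replicate 5 or silica replicates 2, 3 or 4. Of 16 p53 targets 3 rose and none fell (5 higher when adjusted over the list alone, median log2 fold change 0.21, adjusted p = 0.00941, adjusted p = 0.0826 with an estimated correlation). The median was 0.11 without silica replicate 2 and 0.07 without silica replicate 3. The growth factor GDF15 (1.55 ± 0.15) and GADD45A (1.22 ± 0.12), which arrests growth after DNA damage, were the largest, and both are known to respond to ATF4 as well. The death receptor TNFRSF10B (0.81 ± 0.21) followed. The call of TNFRSF10B ended without control replicates 4 or 5 or silica replicates 4 or 5 (adjusted p from 0.0666 to 0.071). The cell cycle inhibitor CDKN1A did not pass the detection filter. With a filter on signal, chosen after seeing the data, its log2 intensity was 9.70 ± 0.18 in control and 10.20 ± 0.19 in silica (n = 5 per group, log2 fold change 0.50 ± 0.14, adjusted p = 0.0348). In the NRF2 list of antioxidant genes (median log2 fold change -0.17, adjusted p = 0.0505), 2 of 28 were higher and 4 lower (2 and 5 when adjusted over the list alone). This list was called lower under 9 of 28 alternatives, among them no background correction and leaving out control replicate 4, and was not called without control replicate 1, which lay 0.405 above the other controls for the median member (adjusted p = 0.177, in a range over all alternatives from 0.00366 to 0.388). Heme oxygenase, HMOX1, rose from 8.56 ± 0.19 to 9.37 ± 0.37 (n = 5 per group, adjusted p = 0.00972). The ferritin heavy chain FTH1 rose by 0.88 ± 0.23 on the log2 scale. The epoxide hydrolase EPHX1 (-0.84 ± 0.16) and the transporter ABCC2 (-0.64 ± 0.15) fell, as did glutathione reductase, GSR (-0.51 ± 0.15), named after its value was seen. The call of FTH1 ended without control replicates 1, 4 or 5 or silica replicates 1, 4 or 5 (adjusted p from 0.052 to 0.0745). The call of GSR ended without any 1 array (adjusted p from 0.0584 to 0.114).

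Metallothioneins are small proteins that bind zinc and other metals. Their list also holds the zinc transporter SLC30A1 and the pseudogene MT1JP, neither of which passed. Of its 8 members 3 were higher and none lower, the same counts as when adjusted over the list alone (median log2 fold change 0.53, adjusted p = 0.00941, adjusted p = 0.177 with an estimated correlation). The log2 fold change was 1.60 ± 0.28 for MT2A, 1.51 ± 0.31 for MT1A and 0.97 ± 0.19 for MT1G, which was above background on 3 control arrays. The metallothionein genes are near-identical in sequence, so a probe may read several of them. Control replicate 1 was low for this list, with a median 1.08 below the mean of the other controls on the log2 scale. Without it the median log2 fold change of the list was 0.29 and those of MT2A, MT1A and MT1G were 1.28, 1.16 and 0.83 (adjusted p of 9.25e-05, 0.000413 and 0.00754). The list's median rose to between 0.80 and 0.93 without control replicate 2, 3 or 4 or silica replicate 4. Ribosomal proteins were called higher as a list (median log2 fold change 0.19, adjusted p = 0.0134, adjusted p = 0.538 with an estimated correlation), although none of the 43 members passed, nor any adjusted over the list alone. The smallest p were those of RPS13 (0.73 ± 0.29, adjusted p = 0.145) and RPL37 (0.37 ± 0.17, adjusted p = 0.208). Control replicate 1 was 0.733 lower than the other controls for the median ribosomal protein. Without it the list's median log2 fold change was 0.0695 and its call ended (adjusted p = 0.344, in a range over all alternatives from 0.00176 to 0.538). Factors of ribosome assembly were called higher (median log2 fold change 0.28, adjusted p = 0.000741), with 2 of 24 members past 5% FDR, RRP12 (0.67 ± 0.14) and RRS1 (0.64 ± 0.12), both also when adjusted over the list alone. Neither passed with median scaling (adjusted p of 0.0713 and 0.0693, in ranges over all alternatives from 0.00303 to 0.0957 and from 0.000609 to 0.0693).

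Lists of cell division genes were called lower. All 33 measured genes of DNA replication and S phase had lower means in silica, and 15 of them passed 5% FDR (25 when adjusted over the list alone, median log2 fold change -0.53, adjusted p = 1.48e-13). The DNA polymerase alpha subunits POLA1 and POLA2 changed by -0.87 ± 0.18 and -0.78 ± 0.15 on the log2 scale. The replication factor CDC45 changed by -0.75 ± 0.14 and UHRF1, which maintains DNA methylation, by -0.66 ± 0.17. Of 40 genes of mitosis 12 fell (25 when adjusted over the list alone, median log2 fold change -0.45, adjusted p = 1.05e-08), among them the kinesin KIF20A (-0.99 ± 0.15), BIRC5 (survivin, -0.78 ± 0.17), DLGAP5 (-0.84 ± 0.21) and the kinase NEK2 (-0.81 ± 0.22). The call of UHRF1 ended without control replicate 4 or silica replicates 1, 2 or 5 (adjusted p from 0.0532 to 0.0658). The call of DLGAP5 ended without control replicates 4 or 5 or silica replicates 1, 3 or 4 (adjusted p from 0.0501 to 0.0605). The call of NEK2 ended without control replicates 2 or 5 or silica replicates 1, 3 or 4 (adjusted p from 0.0747 to 0.0812). The phosphatase CDC25B, named after its value was seen, rose by 0.66 ± 0.13 and was the only member that rose. Its detection p-value was under 0.05 on 4 control and 2 silica arrays, though its mean log2 intensities were 9.99 and 10.65. MKI67, the gene of the Ki-67 proliferation marker, had a mean of 5.57 ± 0.25 in control and 5.12 ± 0.16 in silica (n = 5 per group) and did not pass (adjusted p = 0.0706). It was above background on 4 of the 5 silica arrays. With signal level as a block the 2 lists were still called, and without the 2 bright arrays the medians were -0.54 and -0.47, against -0.46 and -0.29 in the bright pair.

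Lists of lipid and drug metabolism were called lower as well. Fatty acid synthesis had 4 of 16 members lower and none higher (5 lower when adjusted over the list alone, median log2 fold change -0.37, adjusted p = 0.000441, adjusted p = 0.0821 with an estimated correlation), among them ATP citrate lyase, ACLY (-0.71 ± 0.14), acetyl-CoA carboxylase, ACACA (-0.60 ± 0.12), the elongase ELOVL6 (-0.55 ± 0.15) and the desaturase SCD5 (-0.40 ± 0.12). ACACA was above background on 4 silica arrays, at a mean log2 intensity of 8.82 in silica. SCD5 was above background on 4 control and 3 silica arrays, at mean log2 intensities of 6.16 and 5.76. The call of ELOVL6 ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 3 or 4 (adjusted p from 0.0558 to 0.091). The call of SCD5 ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 2, 3, 4 or 5 (adjusted p from 0.0579 to 0.0983). Cholesterol synthesis had 4 of 23 lower and none higher, with 4 lower when adjusted over the list alone (median log2 fold change -0.25, adjusted p = 0.00202, adjusted p = 0.0826 with an estimated correlation). Control replicate 1 lay 0.272 above the other controls for the median member, and without it the median was -0.17. The sterol oxidase MSMO1 (-0.87 ± 0.21) and the sterol isomerase EBP (-0.59 ± 0.17) were among those that fell. MSMO1 was above background on 4 control arrays, at a mean log2 intensity of 8.77 in control. Its call ended with the planned background on all rows and with the block by description number (adjusted p from 0.00814 to 0.107 over all alternatives). The call of EBP ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 2, 3 or 4 (adjusted p from 0.0708 to 0.116). In the xenobiotic list 6 of 16 fell and 1 rose (8 and 1 when adjusted over the list alone, median log2 fold change -0.41, adjusted p = 0.000516). The glutathione peroxidase GPX2 (-1.54 ± 0.18), the drug efflux pump ABCG2 (-1.12 ± 0.17) and the cytochrome P450 CYP4F11 (-0.75 ± 0.14) fell, and the AhR repressor TIPARP (0.66 ± 0.12) rose.

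Lists of matrix, junction and cytoskeleton genes were called lower at the preset correlation. Of 21 TGF-beta and fibrosis targets 7 fell and 2 rose (9 and 3 when adjusted over the list alone, median log2 fold change -0.30, adjusted p = 0.00414, adjusted p = 0.0826 with an estimated correlation). Beside COL1A1, the collagen chain COL5A1 (-1.16 ± 0.21) and the BMP target ID1 (-0.98 ± 0.14) fell, while the matricellular protein CCN1 (0.78 ± 0.16, named after its value was seen) rose. Epithelial junctions were called lower (median log2 fold change -0.19, adjusted p = 0.0208, adjusted p = 0.38 with an estimated correlation), with 3 of 16 lower and 1 higher (4 and 1 when adjusted over the list alone). CDH1 and the tight junction protein CLDN2 (-0.99 ± 0.11) and keratin 8, KRT8 (-0.90 ± 0.22), fell and CLDN1 (0.75 ± 0.20) rose. Without control replicate 1, which lay 0.339 above the other controls for the median junction gene, the junction list was not called (median -0.12, adjusted p = 0.172, in a range over all alternatives from 0.000485 to 0.38). The call of CLDN1 ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 2, 4 or 5 (adjusted p from 0.0537 to 0.0712). The call of KRT8 ended without silica replicates 1, 4 or 5 (adjusted p from 0.0509 to 0.052). Among actin and SRF genes 4 of 22 fell and none rose, also when adjusted over the list alone (median log2 fold change -0.18, adjusted p = 0.000741, adjusted p = 0.101 with an estimated correlation), led by the calponin CNN3 (-0.89 ± 0.13) and talin, TLN1 (-0.89 ± 0.12), with the calponin CNN2 (-0.66 ± 0.16) and the tropomyosin TPM4 (-0.55 ± 0.14). CNN2 had a detection p-value under 0.05 on 3 control and 2 silica arrays, though its mean log2 intensities were 9.27 and 8.61. The call of TPM4 ended without control replicates 2 or 4 or silica replicates 2, 4 or 5 (adjusted p from 0.053 to 0.0648). Mesenchymal markers were not called as a list (median log2 fold change 0.00, adjusted p = 0.691), and 1 of 10, the transcription factor ZEB2 (0.83 ± 0.18, above background on 4 control arrays), rose, also when adjusted over the list alone.

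**Figure D3:**
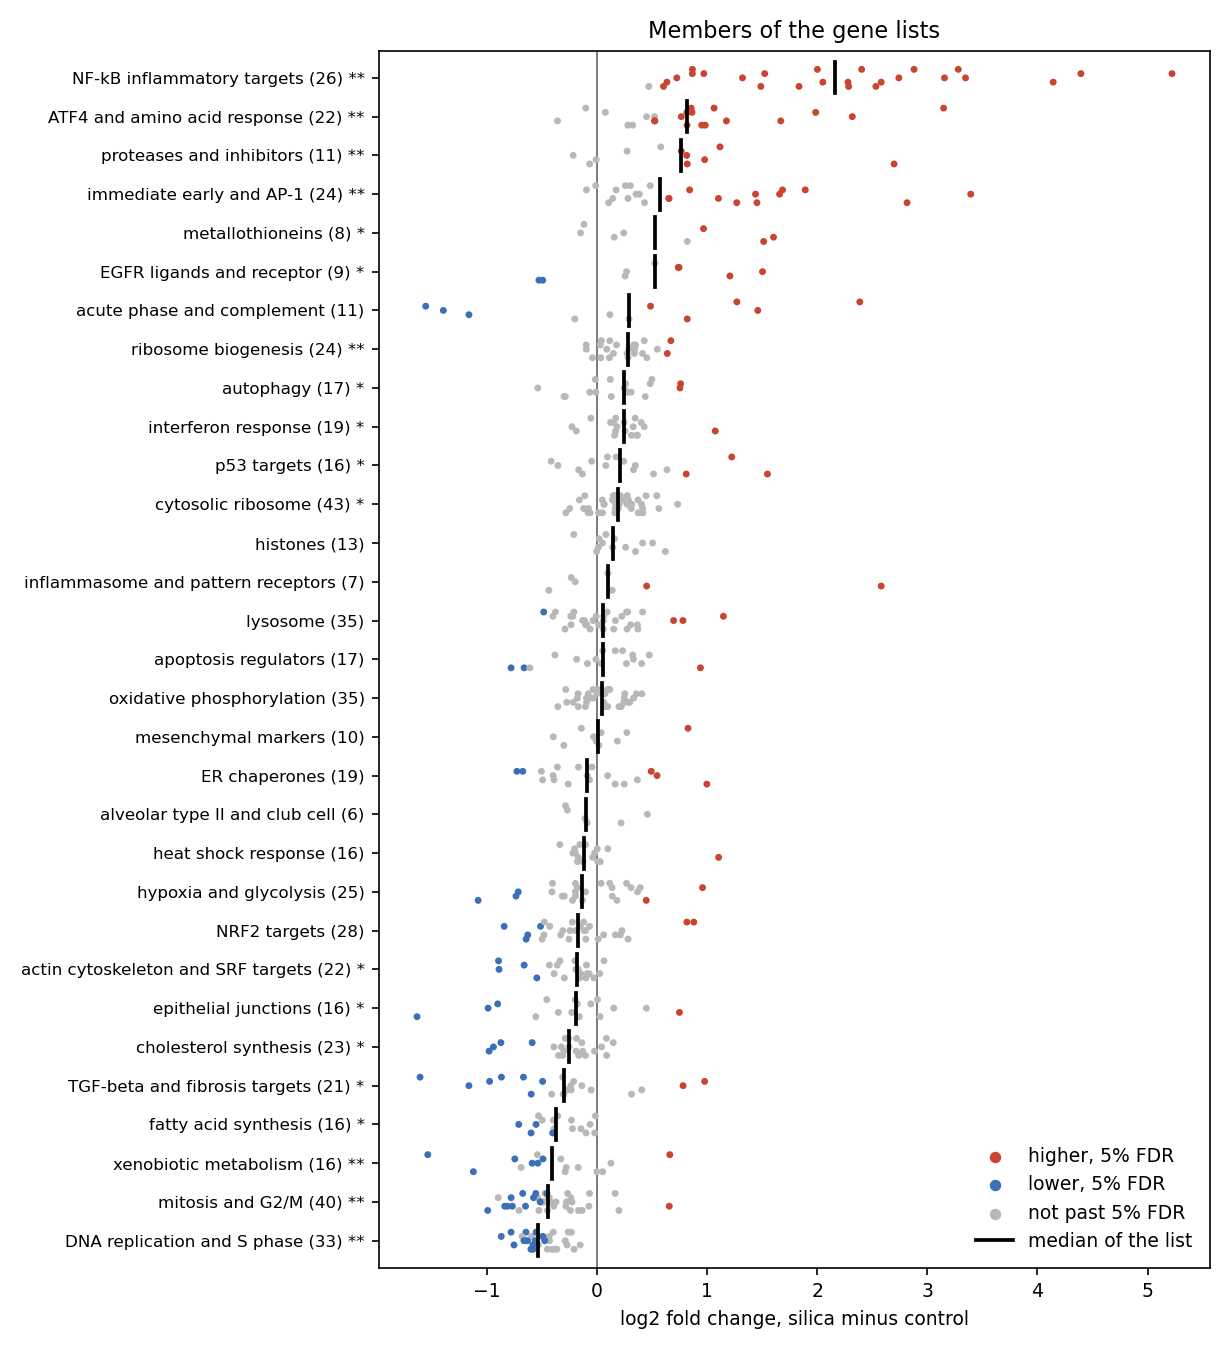
Log2 fold changes (silica minus control, horizontal axis) of the members of 31 gene lists, 1 row per list with its number of measured members. Points are genes, coloured by their call at 5% FDR, black bars are list medians, 1 star marks lists called at a preset correlation of 0.01 and 2 stars those also called at an estimated correlation. The medians run from -0.53 for DNA replication to 2.17 for NF-kB targets, and 19 lists carry a star.

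The interferon list was called higher (median log2 fold change 0.25, adjusted p = 0.00419, adjusted p = 0.0959 with an estimated correlation) with 1 of 19 members past 5% FDR, the exonuclease ISG20 (1.07 ± 0.18), also when adjusted over the list alone. ISG20 is known to respond to NF-kB too. Autophagy was called higher (median log2 fold change 0.25, adjusted p = 0.0271, adjusted p = 0.0826 with an estimated correlation) with 2 of 17 members, the cargo receptors OPTN (0.75 ± 0.12) and SQSTM1 (0.76 ± 0.19), both also when adjusted over the list alone. Acute phase and complement genes were not called as a list (median log2 fold change 0.29, adjusted p = 0.226). Without control replicate 1 the median was 0.09, and without control replicate 3, 4 or 5 it was 0.60, 0.53 and 0.63. The list was called under 5 of 28 alternatives, among them those without control replicate 3, 4 or 5 (adjusted p of 0.0381, 0.0126 and 0.0214, in a range over all alternatives from 0.000407 to 0.788). Its members moved both ways, with 5 of 11 higher and 3 lower, the same counts as when adjusted over the list alone. Lipocalin, LCN2 (2.39 ± 0.15), the complement inhibitors CD55 (1.46 ± 0.18) and CD59 (0.49 ± 0.13), the complement factor CFB (1.27 ± 0.18) and the protease inhibitor SERPINA3 (0.82 ± 0.13) rose. The fibrinogen chains FGB (-1.56 ± 0.17) and FGA (-1.40 ± 0.12) fell. CD59 and CFB were named after their values were seen. LCN2 was above background on 2 control arrays, at a mean log2 intensity of 4.82 in control. FGA and FGB were above background on 3 silica arrays, at mean log2 intensities of 6.98 and 6.30 in silica. The lysosome list (median log2 fold change 0.06, adjusted p = 0.28) had 3 of 35 higher, the cholesterol transporter NPC1 (1.15 ± 0.15), the sialidase NEU1 (0.78 ± 0.18) and the protease CTSL (0.70 ± 0.12), and 1 lower, the glucuronidase GUSB (-0.48 ± 0.14) (4 and 1 when adjusted over the list alone). Hypoxia and glycolysis (median log2 fold change -0.13, adjusted p = 0.567) had 2 of 25 higher and 3 lower (3 and 3 when adjusted over the list alone). The carbonic anhydrase CA9 (-1.08 ± 0.21, above background on 1 silica array), the glycolytic regulator PFKFB3 (-0.74 ± 0.14) and the glucose transporter SLC2A1 (-0.72 ± 0.16) fell, and the enolase ENO2 (0.96 ± 0.13) and the peptide hormone ADM (0.45 ± 0.13, named after its value was seen) rose. CD59 was above background on 3 control and 2 silica arrays, at mean log2 intensities of 7.16 and 7.65. The call of SQSTM1 ended without control replicate 5 or silica replicate 5 (adjusted p from 0.0525 to 0.0534). The call of CD59 ended without control replicate 2 or silica replicates 2 or 4 (adjusted p from 0.0504 to 0.0675). The call of GUSB ended without control replicates 1, 3, 4 or 5 or silica replicates 1, 2, 3, 4 or 5 (adjusted p from 0.0551 to 0.109). That of NEU1 ended with the planned background on all rows and with the block by description number (adjusted p from 0.0057 to 0.149 over all alternatives). The call of ADM ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 2, 4 or 5 (adjusted p from 0.063 to 0.122).

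In the remaining lists few members passed and camera called none. Regulators of apoptosis (median log2 fold change 0.05, adjusted p = 0.691) had 1 of 17 higher and 2 lower (1 and 3 when adjusted over the list alone). MCL1, which protects cells from apoptosis, rose by 0.94 ± 0.24, and APAF1, which assembles the apoptosome, had a log2 fold change of -0.66 ± 0.20. Heat shock genes (median log2 fold change -0.12, adjusted p = 0.706) had 1 of 16 higher, the small chaperone CRYAB (1.10 ± 0.17), also when adjusted over the list alone. The inflammasome list (median log2 fold change 0.10, adjusted p = 0.217) had 2 of 7 higher, IL1B and the receptor adaptor TICAM1 (0.45 ± 0.13), also when adjusted over the list alone. Fry, which does not compare a list with other genes, called it (adjusted p = 7.22e-05, in a range over all alternatives from 7.22e-05 to 0.983). The inflammasome median was below 0 without control replicates 1 or 2 or without any 1 silica replicate (from -0.24 to -0.02). Without control replicate 4 it was 0.155. APAF1 was above background on 4 control and 3 silica arrays and TICAM1 on 1 control and 4 silica arrays. The mean log2 intensities of TICAM1 were 7.30 in control and 7.75 in silica, and those of APAF1 were 7.22 and 6.56. The call of MCL1 ended without control replicate 3 or silica replicates 1 or 5 (adjusted p from 0.0534 to 0.0677). The call of APAF1 ended without control replicates 2, 3, 4 or 5 or silica replicates 1, 2, 4 or 5 (adjusted p from 0.0613 to 0.121). The call of TICAM1 ended without control replicates 3, 4 or 5 or silica replicate 2 (adjusted p from 0.0797 to 0.0989). No member passed, and none adjusted over the list alone, among 13 histones (median log2 fold change 0.14, adjusted p = 0.202), 35 genes of oxidative phosphorylation (median log2 fold change 0.04, adjusted p = 0.706) and 6 genes of alveolar type II and club cells (median log2 fold change -0.10, adjusted p = 0.942). Those with the smallest p were the histones H2BC11 (0.62 ± 0.26) and H4C8 (0.50 ± 0.23), the respiratory chain members ATP5F1A (-0.36 ± 0.13) and NDUFB5 (-0.28 ± 0.13), and the lung genes CEBPA (0.46 ± 0.18) and MUC1 (-0.29 ± 0.15), with adjusted p from 0.0963 to 0.276. Without control replicate 1 the medians were 0.01 for histones and -0.05 for oxidative phosphorylation. Control replicate 1 lay 0.63 and 0.518 below the other controls for the median histone and the median gene of oxidative phosphorylation. GAPDH, a common reference gene, was 12.67 ± 0.21 in control and 12.54 ± 0.13 in silica (n = 5 per group, adjusted p = 0.611). Markers of cells other than A549 were too few above background to test as lists. Of 22 leukocyte markers 3 were measured (CD14, CD68 and LYZ), of which the macrophage and lysosome protein CD68 rose (1.21 ± 0.14) and the endotoxin receptor CD14 fell (-0.99 ± 0.13). Of 19 fibroblast and endothelial markers 4 were measured (COL1A1, COL3A1, ESAM and THY1), of which COL1A1 and COL3A1 (-1.23 ± 0.13) fell. CD14 was above background on 4 control arrays, at a mean log2 intensity of 6.83 in control, and COL3A1 on 4 silica arrays.

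Of the 31 lists tested with camera, 19 were called at 5% FDR with a preset correlation of 0.01 between genes (11 higher, 8 lower). With an estimated correlation 8 held, those of NF-kB targets (adjusted p = 1.45e-05), immediate early genes (0.00234), mitosis (0.00234), proteases (0.00572), the ATF4 response (0.017), xenobiotic metabolism (0.017), ribosome assembly (0.017) and DNA replication (0.0214). The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.166.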

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

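The tests of control replicate 1 as a whole, and of what it does to the metallothionein, ribosomal protein and cell division lists, were chosen after the results were seen. The counts over other splits of the arrays and the test of the bright arrays were set out before theirs.

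In each group of 5 arrays, the gap between the most distant array and its neighbour was divided by the range, and gaps above 0.71 are given here. Of 254 such groups 20 passed, where chance gives about 12.7, or 1 in 20. The median intensity of replicate 2 was far above the others in control (gap 0.929 of the range) and in silica (0.946). The mean correlation with its own group was low for control replicate 1 (0.91) and silica replicate 3 (0.791). Control replicate 1 was low for MT2A (0.914), MT1A (0.81) and PLAUR (0.893) and high for CLDN1 (0.818), CCN1 (0.805), UHRF1 (0.753), KRT8 (0.83) and GSR (0.842). Control replicate 2 was low for RPL37 (0.732). CSF2 was high in control replicate 5 (0.771) and FGA low in control replicate 3 (0.736). Silica replicate 3 was high for MT1A (0.735), DUSP5 (0.715) and CDC25B (0.79). Silica replicate 2 was low for EREG (0.798), and silica replicate 5 was low for LPAR5 (0.747). Over all 10137 genes, control replicate 1 was the distant array for 8.78% and silica replicate 3 for 2.92%, against 0.385% to 0.986% for the other 8 arrays.

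Rows without a gene symbol were left out of the comparison. When all 11012 detected rows were tested together, 25 of the 832 rows without a symbol passed 5% FDR, 7 higher and 18 lower in silica. That was 3% of them, against 9.65% of rows with a symbol.

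Of 100 splits of the 10 arrays into 5 and 5, drawn from 126 with the real one included, 1 gave as many genes past 5% FDR as the real 998, the real one itself, and the highest of the others gave 1. For genes past 5% FDR and 1.5-fold the number was also 1, with 722 real and 1 at most in the others. For both counts the real grouping thus ranked first, under the limit of 5% set beforehand. That argues against an arbitrary grouping of these arrays as the source of either count. A difference between the groups other than silica, such as a shared culture or batch, would rank the same and stays open. For gene lists called at the preset correlation, 3 splits gave at least the real 19, and the highest other gave 19. This was under the limit of 5% as well, though narrowly. The 2 other splits exchanged 1 array of each group, which leaves most of the real difference in place. The 82 splits that mixed the groups further called a median of 5 lists and at most 9. Part of the silica difference stays in these splits, between and within their 2 sides, so their counts do not give the error rate of either correlation.

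Control replicate 1 stood apart from the other 4 controls. The SD of its deviation from their mean was 0.558 across genes, against 0.265 to 0.322 for the others, each set against the remaining 3. Noise confined to dim genes is argued against, since the SD was 1.97 times as large among the brightest 20% of genes as among the dimmest. This ratio cannot exclude an array with weak signal among its bright genes. The mean raw intensity of control replicate 1 was 149.6, against 171.6 to 593.1 on the other arrays. Its highest raw intensity was 18812.1, against at least 22511.8 on the others, while its median of 71.2 was not the lowest. A weak signal of control replicate 1 thus stays open. A mislabelled silica sample is argued against too, as over the 1136 genes called without this array it lay at 0.0909 on the axis from the other controls (0) to the silica arrays (1). A loss of short transcripts remains a candidate explanation, because the deviation rose with gene length (Spearman's rho = 0.292 across 9572 genes, which are not independent replicates, against -0.0867 to 0.0816 in the other controls), though the length is that of the gene on the genome and not of its transcript, and no biological explanation was tested.

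Metallothioneins and ribosomal proteins were called higher in silica as lists at the preset correlation but not at an estimated one (adjusted p of 0.177 and 0.538), and control replicate 1 was low for both. Without it the median log2 fold change of ribosomal proteins was 0.0695, against 0.191 with it, and the list was no longer called, so that call may rest on this array. For metallothioneins the array does not account for the whole rise, since at the preset correlation the list was still called without it (median 0.294, against 0.531 with it, adjusted p = 0.00624 at the preset and 0.0641 at an estimated correlation, in a range over all alternatives from 0.00441 to 0.177). A response of metallothioneins to silica stays open, as does how many of these genes changed, since near-identical copies may share probes.

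The lists of DNA replication and of mitosis were lower in silica. Neither the bright arrays nor control replicate 1 accounts for this. Without both bright arrays the median log2 fold changes were -0.544 and -0.474, without control replicate 1 they were -0.463 and -0.391, and each list was called in each case. Slower division under silica is a hypothesis that these values are consistent with. Differences in cell density or cell death between cultures were not tested, and would also change these lists.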

How the results depend on the processing

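Alternatives with signal level as a block, without the 2 bright arrays or with a filter on signal were chosen after seeing the data, and the planned background on all rows was made an alternative then. No result changed direction past its threshold under any alternative. Of the 123 genes named by the rule or after their values were seen, 113 were called, and 61 of these stayed past 5% FDR wherever they were tested. Leaving out 1 array or another ended the calls of 23. The block by description number over 8 arrays, which changes both the arrays and the model, ended 47 of their calls. Median scaling ended 19, the fit without the 2 bright arrays 21 and the background on all rows 15. Leaving out 1 array gave 717 to 1136 genes past 5% FDR against 998, 633 to 745 past 5% FDR and 1.5-fold against 722, and 17 to 21 lists against 19. The most genes came without control replicate 1, and 884 of them were among the 998. Array weights, which gave that array 0.231, called 1421.

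Within the 8 arrays other than the bright pair 281 genes were higher and 268 lower past 5% FDR, 528 of them among the 998. With the description number block 264 passed, where fewer arrays enter and a block is fitted as well. The count past 5% FDR and 1.5-fold was 293 with no background correction, 395 with normexp and an offset of 50 and 293 with the background fitted on all rows. In the authors' value table it was 211, of which 64% were higher against 49.2% in the comparison reported. The cause was not tested for these 4. It was 475 of 6048 genes with detection p under 0.01 on all 10 arrays, where fewer genes are tested, and 264 with the description number block. The number of lists fell to 8 for camera with estimated correlation. Fry called 19, 18 of them the same, without the ribosomal proteins (adjusted p = 0.308) and with the inflammasome list (adjusted p = 7.22e-05). Of the 19 lists called, 8 kept the call throughout, and 3 others (NRF2 targets, acute phase, inflammasome) gained one under at least 1 alternative. A replicate block on the title numbers called 763 genes, 666 past 1.5-fold and 20 lists. The deviations of arrays with the same title number correlated between -0.0694 and 0.144, and those with the same description number between -0.0876 and 0.144. These values do not show a pairing by either number, but cannot exclude one. Arrays of unlike number were not compared, and quantile normalization had removed differences in brightness. Both bright arrays carry title number 2, so pairing by title number stays open. Chip as a batch was not run, since the chips are not given in the sources used here. Signal over background limits what was seen, with at most 33.5% of rows detected on an array.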

Other observations

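Both gene lists and the test of gene length in this part were chosen after the comparison of silica with control had been seen.

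Several of the largest decreases were genes better known from liver and gut, such as BAAT, CDH17, TM4SF4, FGA and FGB, which A549 cells expressed here. To ask whether others of this kind moved with them, a list of 51 liver-type genes was written that left out those already seen. Of its 10 measured members 8 had lower means in silica, 5 fell at 5% FDR over all genes and none rose (median log2 fold change -0.381, camera adjusted p = 0.00085 over both lists of this part, unadjusted p = 0.013 with an estimated correlation). The anticoagulant proteins PROS1 (-1.23 ± 0.16 on the log2 scale, ± SE) and PROC (-1.18 ± 0.22, above background on 2 silica arrays) and the transcription factors FOXA1 (-0.63 ± 0.12) and FOXA3 (-0.54 ± 0.15) fell. The RNA editing cofactor A1CF was not above background on any silica array and was at least 1.4-fold lower on the background-corrected scale, and the list's median was -0.35 with it at this bound. Its fitted log2 fold change was -0.31 without background correction and -0.05 with the planned background on all rows. The call of FOXA3 ended without control replicates 1, 4 or 5 or silica replicates 1, 2, 3 or 5 (adjusted p from 0.0525 to 0.0862). Without control replicate 1 the list's median was -0.242 (camera unadjusted p = 0.00136, and 0.0212 with an estimated correlation). HNF4A (-0.14), TTR (-0.15) and NR5A2 (-0.22) did not pass, and neither did AMBP (0.31) and APOE (0.20), whose means were higher. In the acute phase and complement list, which holds FGA and FGB, 5 of 11 members rose (LCN2, CFB and SERPINA3 among them) and 3 fell. That silica lowered a liver-like program of these cells is thus a hypothesis that rests on part of the liver-type list. No protein or activity of a transcription factor was measured.

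AXIN2 was the third largest decrease, so other Wnt targets were tested for a shared fall. Of 12 measured targets 2 rose and 1 fell at 5% FDR (CD44 and NKD2 higher, LGR4 lower), 6 of them had lower means, and the list was not called (median log2 fold change -0.0204, camera adjusted p = 0.621). As the members went both ways, this neither shows nor excludes a fall in Wnt signalling.

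Across 9572 genes the log2 fold change fell with gene length over all 10 arrays (Spearman's rho = -0.14, across genes, which are not independent replicates). Without control replicate 1 rho was -0.0337 across 9282 genes. Of all 126 splits of these 9 arrays into 4 and 5, 63 gave a rho at least as large in size, the real one included (exact permutation p = 0.5, two-sided). A relation with gene length was thus not shown apart from that array.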
